A study of Mus musculus with 3 samples.

How the data were processed

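The starting point was a table of expression values per gene, with 1 column for each of 3 libraries, made from sorted thymic cells of 19-day-old mice of a mixed 129sv/C3H background. The cells were lineage-negative, CD44-positive and CD25-negative (the DN1 gate), and the wild type library pooled cells of 2 mice while the gl/gl and the CD2-Ostm1 gl/gl libraries each pooled cells of 3 mice, per the labels. Each column was matched to its library by the name in the table's header, and each library to its genotype by its label.

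Per the submitters' processing notes, TopHat2 version 2.0.10, Cuffdiff version 2.2.1 and the mouse build mm10 were used. The gene annotation and the strand setting are not given in the sources used here. The deposited values were read as FPKM (fragments scaled for transcript length and for the mapped fragments of the library), because Cuffdiff writes that unit and the highest values belonged to very short RNAs, although the header of the deposited table does not name a unit. Libraries were compared on the scale of the deposited values, and how the authors scaled libraries to each other is not stated. Positions in the table count from 0 at the start: among 21340 genes matched by symbol and chromosome to an annotation of the same build, the start plus 1 equalled the annotated start for 10534. Positions are given here counted from 1.

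The table held 23352 lines. An empty line (1 in all) was not analysed here, 3 lines with a cell that was no number were left out, and 23348 lines were used, of which 98 name more than 1 gene. No read counts were used, so depth was estimated from the spacing of the lowest values of genes with a single annotated transcript, assuming fragments of 200 bases. A single fragment on 1 kb was worth about 0.0199 FPKM in wild type, 0.0324 in gl/gl and 0.0372 in CD2-Ostm1 gl/gl. At 5 FPKM, a transcript of 2 kb then had about 502, 309 and 269 fragments in the 3 libraries. These are rough estimates and cover counting error only.

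Fold changes were differences of log2(FPKM + 1), a scale that understates the change of low genes. A gene counted as measured at 1 FPKM or more in at least 1 of the 3 libraries, which 12849 genes met. A gene counted as higher or lower at 2-fold or more on this scale. With 1 library per genotype there is no replicate, so no spread between replicates, no test of the genotypes and no p-value was computed. The rule for named genes took Ostm1 and Clcn7, then for each comparison the 10 highest and the 10 lowest fold changes among genes at 5 FPKM or more in at least 1 of the 2 libraries compared, leaving out symbols of predicted genes, clones, small RNAs and pseudogenes by fixed patterns, and then up to 4 members of each gene list with the greatest absolute fold change. The patterns did not cover Rnu73b and AF357399, which stayed in. Some genes that meet the rule are not reported here. Genes named outside this rule were chosen after their values were seen: the Y-linked genes, Cpa3, Sfpi1, Rn45s, Snora33, Clec4e, Cd63, Alox5, Slc45a3, Tph1, Kcne3, Elane, Prtn3, Amd1 and Amd2, the separate Eif3j2 entry, members named to spell out a small count, and genes of 1 comparison named again in another. Gata2, Ms4a2, Hdc and Fcer1a were chosen in the same way.

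A set of 34 gene lists (13 of cell types, 17 of pathways and 4 of RNA quality, 546 entries in all) was written beforehand, and 42 entries had no line in the table. The list of mitochondrially encoded genes had no line there and gave no value. For each other list with at least 3 measured members, the median fold change was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called above or below the random range when its median fell outside the central 95% of those medians. This describes the libraries and does not test the genotypes. The gl/gl and CD2-Ostm1 gl/gl libraries were both compared with the same wild type library, so the overlap between both comparisons was set beside 100 simulated draws in which the 3 libraries differed by independent noise. That noise was drawn from the whole difference between the CD2-Ostm1 gl/gl and wild type libraries, within bins of expression, and so takes that whole difference as noise. The overlap of independent lists is the product of both numbers of genes divided by the number measured.

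The groups, the comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The alternatives were other pseudocounts (0.1 and 5), other filters (none, or 5 FPKM), rescaling by the median of gene ratios or to an equal upper quartile, and thresholds of 1.5-fold and 4-fold. Counts without predicted genes, clones and small RNAs, and without genes on the X and Y chromosomes, were added after seeing the data. The code of the counting rule was tested on simulated data with a small assumed noise, equal for all genes, which does not stand for the differences between pools. Of genes given a log2 change of 1.5 and of -1.5, 100% and 97.9% were called in that direction in a simulated comparison of gl/gl with wild type, 100% and 95.7% for CD2-Ostm1 gl/gl with wild type, and 98.2% and 98.1% for CD2-Ostm1 gl/gl with gl/gl. In each simulated comparison 100% of the genes given 3 or -3 and 0% of 12649 genes given no change were called, which is no estimate of false calls, since the noise drawn from the libraries put about 213 and 211 genes past 2-fold. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.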

Results

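The DN1 gate holds the earliest progenitors of the thymus together with other lineage-negative cells. RNA of DN1 cells was compared between wild type mice, osteopetrotic grey-lethal mice (gl/gl, which lack Ostm1, a partner of the lysosomal chloride transporter Clcn7) and gl/gl mice carrying an Ostm1 transgene under CD2 control. There was 1 library per genotype, each from pooled mice, so no difference below has a replicate check. The wild type, gl/gl and CD2-Ostm1 gl/gl libraries held 11745, 12073 and 12010 genes at 1 FPKM or more and, by a rough estimate from the lowest values, about 502, 309 and 269 fragments on a 2 kb transcript at 5 FPKM. Across 12849 measured genes, which are not independent replicates, log2 values had a correlation of 0.937 between wild type and CD2-Ostm1 gl/gl, 0.864 between wild type and gl/gl, and 0.856 between gl/gl and CD2-Ostm1 gl/gl.

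Ostm1 (chromosome 10, 42678916 to 42702462, mm10) had 19.6 FPKM in wild type, was listed at 0 in gl/gl and had 5.35 FPKM in CD2-Ostm1 gl/gl, 27.4% of the wild type value. Clcn7 (chromosome 17, 25133394 to 25162099) had 8.94, 12.5 and 9.04 FPKM in the same order. None of the 8 measured members of the list of chloride channels and vesicular CLC transporters differed by 2-fold in any comparison, and the median was 0.21 for gl/gl against wild type. The 3 libraries also differed in sex-linked transcripts. Xist, the RNA of the inactive X chromosome, had 116 FPKM in wild type, 0.184 in gl/gl and 235 in CD2-Ostm1 gl/gl, while the Y-linked Eif2s3y had 0.0338, 59.8 and 0.0395 FPKM. Ddx3y, Kdm5d and Uty, also Y-linked, had 34.8, 12.3 and 11.8 FPKM in gl/gl and less than 1 FPKM in both other libraries. Sex-linked transcripts therefore separated the gl/gl library from both others, and the effects of sex and of the gl/gl genotype cannot be separated with these libraries.

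**Figure D1:**
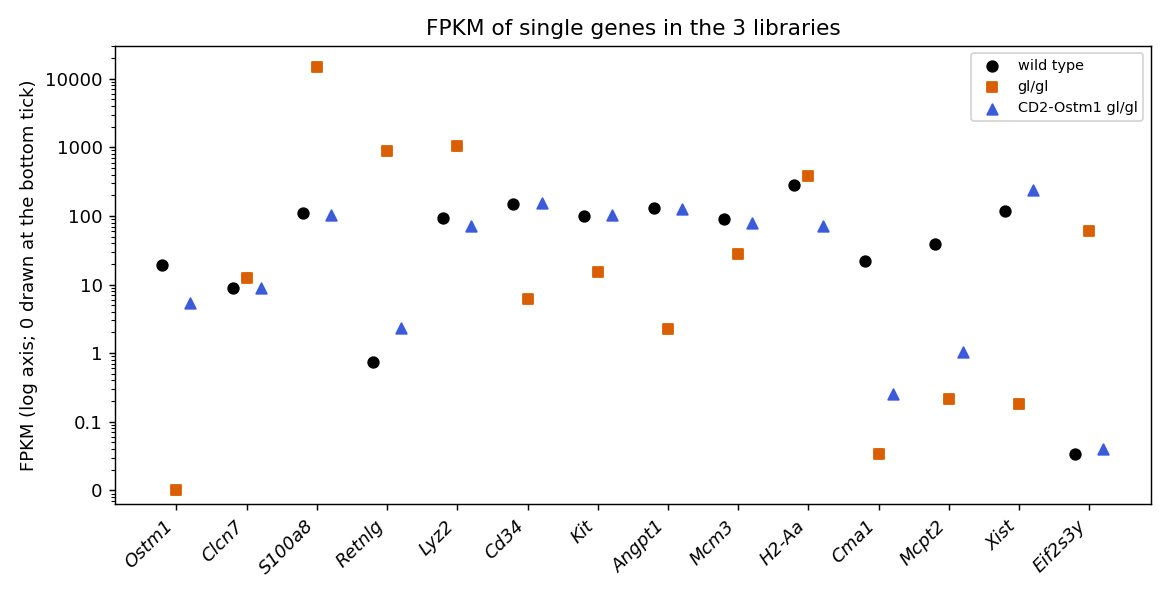
FPKM of 14 genes (log axis) in the wild type (circles), gl/gl (squares) and CD2-Ostm1 gl/gl (triangles) libraries, 1 point per library, with values listed at 0 drawn at the bottom tick. Ostm1 is listed at 0 only in gl/gl, S100a8 reaches 14728 FPKM there, and Cd34 has 149, 6.17 and 153 FPKM.

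The comparison of gl/gl with wild type describes how the DN1 library of mice lacking Ostm1 differed from that of wild type mice. Most granulocyte genes were far higher in gl/gl: S100a8 and S100a9, which form calprotectin, had 14728 and 9344 FPKM against 110 and 82.6 in wild type, and Lcn2, an iron-scavenging protein, had 634 against 4.24. Transcripts of early progenitors were lower: Cd34 (chromosome 1, 194938821 to 194976959), a surface marker of progenitors, had 6.17 FPKM against 149, Kit, the receptor of stem cell factor, 15.3 against 101, and Angpt1, the ligand of the Tie2 receptor, 2.24 against 132. Transcripts of DNA replication were lower too, with Mcm3, a subunit of the replicative helicase, at 27.8 FPKM against 91.5. Of the 12849 measured genes, 1048 were at least 2-fold higher and 790 at least 2-fold lower in gl/gl. The Y-linked Eif2s3y was at 59.8 FPKM in gl/gl and 0.0338 in wild type, so each of these differences also lies between libraries that differ in sex-linked transcripts.

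The 10 genes with the highest fold changes were Rnu73b, a small RNA gene listed at 0 in wild type and at 8760 FPKM in gl/gl, and Stfa3, Retnlg, Stfa2, Stfa1, Stfa2l1, Ifitm6, S100a8, Lcn2 and Mmp8, with log2 fold changes from 6.85 for Mmp8 (neutrophil collagenase) to 9.04 for Stfa3. All 8 genes listed at 0 in wild type and at 5 FPKM or more in both other libraries were small RNAs or predicted genes. The change of Rnu73b is therefore uncertain. The Stfa genes encode stefin A protease inhibitors, and as close copies of each other they may share reads, so their separate values are uncertain. The 10 lowest were Xist, Angpt1, Mcpt2, Gpr56, Mcpt1, Dntt, Egfl7, Cma1, Cd34 and Ostm1. Among them, Dntt, the terminal transferase of antigen receptor gene assembly, had 18.7 FPKM against 462, a log2 fold change of -4.56, and Gpr56, an adhesion receptor, had 5.07 against 165, a log2 fold change of -4.78. Mcpt1, Mcpt2 and Cma1 encode mast cell proteases of 1 gene family and had log2 fold changes of -4.58, -5.04 and -4.46, and reads shared within this family make the separate values uncertain.

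In the granulocyte list 10 of 14 measured members were at least 2-fold higher and 4 were lower, with a median log2 fold change of 5.07, while random lists lay between -0.41 and 0.29. The 4 lower members were Mpo, Cpa3, Ctsg and Mcpt8, and Mpo, myeloperoxidase, had 9.71 FPKM against 152, whereas Elane and Prtn3, proteases of primary granules, were higher with log2 fold changes of 2.46 and 2.35. In the monocyte and macrophage list 12 of 15 were higher and none lower (median 1.599), among them Cd14, a lipopolysaccharide co-receptor, with 36.3 FPKM against 1.43, and Lyz2, lysozyme, with 1038 against 91.7. Natural killer and innate lymphoid genes had 9 of 15 higher and none lower (median 1.03), such as Ncr1, an activating receptor, with a log2 fold change of 2.44, and Tbx21, a transcription factor, with 2.16. In the B cell list 8 of 14 were higher and 3 lower (median 1.20). Cd79a, a part of the B cell receptor, had a log2 fold change of 2.71. The 3 lower members were Vpreb1, Vpreb3 and Igll1, with only 1.35, 1.92 and 1.91 FPKM in wild type, the last listed at 0 in gl/gl. The thymic stroma and osteoclast lists had medians of 0.74 and 0.50, with 3 of 13 and 3 of 9 members higher, and Ostm1 as the 1 lower member of the osteoclast list. The higher osteoclast members were Mmp9, Acp5 and Atp6v0d2, with 159, 80.9 and 1.62 FPKM against 1.19, 20.2 and 0.305. Those of stroma were Krt18, Epcam and Cdh5, with 42.2, 7.39 and 2.39 FPKM against 12.5, 2.34 and 0.259.

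Genes of progenitors and of the cell cycle made up most of the lower lists. Of 17 early progenitor genes 14 were lower and 1 higher (median -1.85, random lists from -0.36 to 0.25). The transcription factors Hoxa9, Mycn and Erg had log2 fold changes of -3.44, -2.97 and -2.90, and the exception was Cebpa, a myeloid transcription factor, at 1.17. Of 18 genes of DNA replication and S phase 14 were lower and none higher (median -1.38), and of 19 mitosis genes 3 were lower (median -0.80), with Top2a at -1.22. In the list of cholesterol synthesis 7 of 15 were lower (median -0.91), with Sqle, squalene epoxidase, at -2.08. The T cell commitment list had a median of 0.01, inside the random range, and its 4 lower members were Hes1, Rag2, Rag1 and Notch1, with log2 fold changes of -2.83, -2.35, -2.19 and -1.36.

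Interferon response genes were higher in 12 of 18 cases and lower in none (median 1.21), led by Ifit3 with 47.1 FPKM against 5.65. Inflammatory genes had 7 of 13 higher and 1 lower (median 1.04), with Il1b, a cytokine, at a log2 fold change of 3.62, Ccl5, a chemokine, at 3.30, and Il6 as the lower member at -1.34. In the same library the monocyte and macrophage and the granulocyte lists had medians of 1.599 and 5.07, beside all lists of this paragraph. Glucocorticoid response genes had 7 of 12 higher (median 1.14), such as Klf9 at 16.4 FPKM against 3.45, and genes of p53 and cell death 4 of 15 higher (median 0.67), such as Bbc3, a pro-apoptotic BH3 protein, at 2.19 and Bcl2, a survival protein, at 2.06. Lysosome genes had 5 of 29 higher and none lower (median 0.46), with Grn, progranulin, at 1.76 and Ctsb, cathepsin B, at 1.29. The autophagy list (median 0.32) had Wipi1 higher at 1.31 and Gabarapl1 lower at -1.67, and the homing and cytokine receptor list (median 0.51) 1 higher and 2 lower, with Cxcr4 at 1.17, Kit at -2.65 and Flt3 at -1.12.

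Of the 33 lists with enough members, 13 lay above and 4 below the random range, where 1.65 would lie outside it for lists of unrelated genes. Members of a list can vary together with the cells of a pool, and some genes stand in several lists. More lists than this may therefore lie outside between pools of equal genotype, and how many was not tested. The other lists lay inside it: later alpha-beta T cell (median -0.19), gamma-delta T cell (-0.08), dendritic cell (0.11), erythroid (-0.32), platelet (-0.39), Notch targets (0.29), Wnt targets (-0.03), unfolded protein response (-0.18), immediate-early and heat shock (0.30), glycolysis (-0.04), oxidative phosphorylation (-0.42), ribosomal proteins (-0.42), reference genes (-0.28) and histones (-0.28), beside the T cell commitment and chloride channel lists. With a pseudocount of 5 the counts became 520 higher and 347 lower. The stroma (0.76), osteoclast (0.50) and autophagy (0.22) medians lay inside the random range with a filter of 5 FPKM, as osteoclast genes (0.52) did with a pseudocount of 0.1, while the dendritic cell (0.47) and immediate-early medians (0.33) lay outside with that filter.

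**Figure D2:**
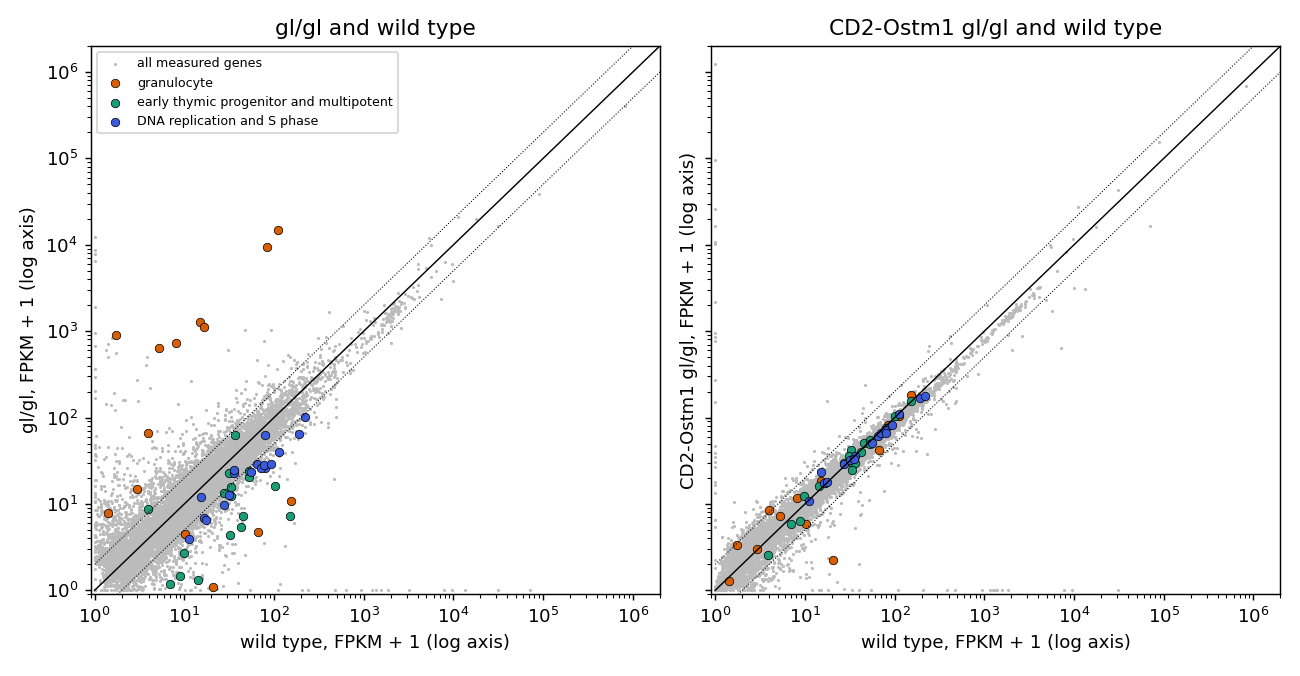
FPKM + 1 (log axes) of 12849 measured genes in gl/gl (left) and CD2-Ostm1 gl/gl (right) against wild type, with members of 3 gene lists coloured, equality drawn as a solid line and 2-fold differences as dotted lines. In gl/gl, 14 of 17 early progenitor genes and 14 of 18 genes of DNA replication and S phase lie below the lower dotted line, and none of either list does in CD2-Ostm1 gl/gl.

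The comparison of CD2-Ostm1 gl/gl with wild type addresses what remained different in gl/gl mice that carried the transgene. Some protease genes of mast cells and basophils were lower: Cma1, a chymase, had 0.251 FPKM against 21.8 in wild type, and Mcpt8, a basophil protease, had 1.23 against 19.7, whereas Cpa3, the mast cell carboxypeptidase, had 40.6 against 65.6, under 2-fold. Most genes of the dendritic cell list were lower as well, with H2-Aa, a class II chain, at 72.0 FPKM against 280, and Cd74, the invariant chain, at 148 against 471. Early progenitor genes were close to wild type, as Cd34 had 153 FPKM against 149 and Kit 102 against 101. In all, 172 genes were at least 2-fold higher and 215 at least 2-fold lower, with Xist at 235 FPKM against 116.

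The 10 highest fold changes belonged to Rnu73b and AF357399, both listed at 0 in wild type, and to Olfr164, Lars2, Stfa3, Hist1h2ah, Vpreb3, Fam196b, Olfr649 and Gpr97. The change of the small RNA gene Rnu73b is uncertain, as stated above, and so is that of AF357399, listed at 0 in gl/gl too and at 150 FPKM in CD2-Ostm1 gl/gl. Lars2, a mitochondrial leucyl-tRNA synthetase, had 237 FPKM against 46.1, and Gpr97, an adhesion receptor gene, 39.7 against 11.5, while the olfactory receptor and histone genes belong to large families and their values are uncertain. The 10 lowest were Mcpt1, Mcpt2, Cma1, Hist1h3b (listed at 0 in CD2-Ostm1 gl/gl), Mcpt4, Mcpt8, Ifi205, a joint entry of Eif3j1 and Eif3j2, Tpsb2 and Naaa. Naaa, a lysosomal amidase, had 4.20 FPKM against 34.9. A separate entry of Eif3j2 at the same position had 30.9 FPKM against 15.3, so reads may be shared between these entries.

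In the dendritic cell list 8 of 15 members were lower and 1 higher (median -1.09, random lists from -0.26 to 0.12). H2-Ab1, H2-Aa and Batf3, a transcription factor of dendritic cells, had log2 fold changes of -2.08, -1.94 and -1.90, and the higher member was Siglech, a marker of plasmacytoid dendritic cells, at 1.47. Erythroid genes had 5 of 8 lower (median -1.17), among them Car1 at -2.72. Other lower ones were low in wild type: Klf1 had 1.84 FPKM there, and the joint entries of Hba-a1 and Hba-a2 and of Hbb-b1 and Hbb-b2 had 3.70 and 1.54. B cell genes had 3 of 14 higher and none lower (median 0.76), among them Vpreb3 at 1.86 and Pax5 at 1.03, with 1.92 and 1.54 FPKM in wild type. Glucocorticoid response genes had 3 of 12 lower (median -0.49), with Il7r, the interleukin 7 receptor, at -1.42. The others were the metallothioneins Mt1 and Mt2, with only 3.25 and 1.11 FPKM in wild type, and Mt2 was listed at 0 in CD2-Ostm1 gl/gl. Monocyte and macrophage genes had 2 of 15 lower (median -0.36), the complement genes C1qc and C1qa at -1.74 and -1.43, and thymic stroma 4 of 13 lower (median -0.26), such as Krt5, a keratin, at -1.92. In the granulocyte list 1 of 14 was higher and 1 lower (median 0.06, inside the random range), with Cxcr2 at 1.11 and Mcpt8 at -3.21, and S100a8 had 103 FPKM against 110. The natural killer list (median -0.23) lay inside as well, with Klrb1c, Id2 and Gzmb lower.

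The lists of mitosis (median -0.22), cholesterol synthesis (-0.45), autophagy (-0.34), T cell commitment (-0.31), unfolded protein response (-0.36) and glycolysis (-0.31) lay below the random range without any member at 2-fold. Interferon response lay above it with a median of 0.12 and no member at 2-fold. The homing and cytokine receptor list also lay above it although its median was negative (-0.06), because the matched random lists were lower still, and its median was 0.0137 after rescaling by the median of gene ratios. In total 3 lists lay above and 11 below, and early progenitor and S phase genes, with medians of 0.02 and -0.07, lay inside. Without predicted genes, clones and small RNAs 80 genes were higher and 162 lower, and with a pseudocount of 5 the counts were 49 and 91. The balance turned with a pseudocount of 0.1 (505 higher, 425 lower), at a threshold of 1.5-fold (672 and 548) and, narrowly, after rescaling by the median of gene ratios (201 and 196), so neither direction is called the more frequent.

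**Figure D3:**
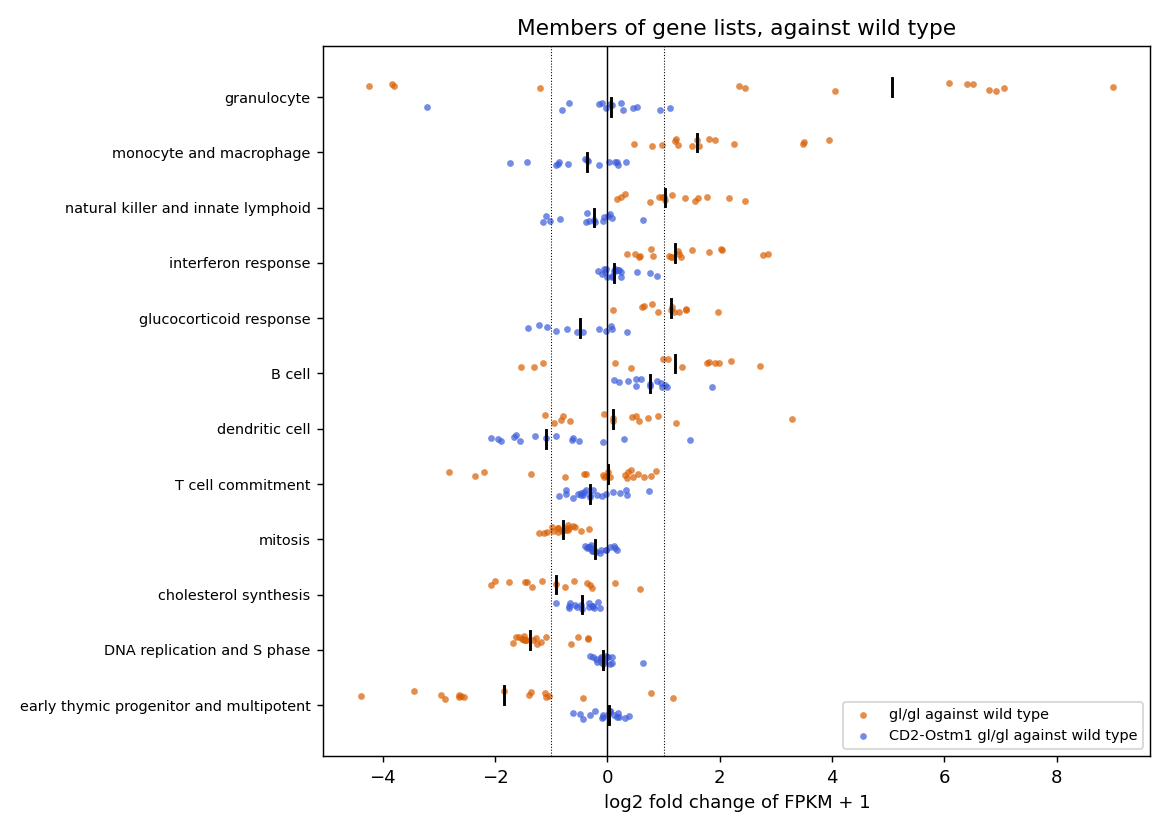
Log2 fold change of FPKM + 1 of each measured member of 12 gene lists, for gl/gl (orange) and CD2-Ostm1 gl/gl (blue) against wild type, with black bars at the list medians and dotted lines at 2-fold. The granulocyte median is 5.07 in gl/gl and 0.06 in CD2-Ostm1 gl/gl, and the early progenitor median is -1.85 and 0.02.

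The comparison of CD2-Ostm1 gl/gl with gl/gl describes how the library of gl/gl mice carrying the transgene differed from that of gl/gl mice without it. Progenitor genes were higher with the transgene: Cd34 had 153 FPKM against 6.17 and Kit 102 against 15.3. Most granulocyte genes were lower, with S100a9 at 80.7 FPKM against 9344 and Lcn2 at 6.16 against 634. At least 2-fold differences were found for 831 genes higher and 1262 lower. These libraries differed in sex-linked transcripts as well, Xist being at 235 FPKM against 0.184 in gl/gl.

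Beside Xist and AF357399 (listed at 0 in gl/gl), the 10 highest fold changes were those of Angpt1, Gpr56, Egfl7, Pdgfrb, Cd34, Slc35d3, Mpo and Gfra1, from 4.07 for Gfra1, a receptor of glial-derived factors, to 5.30 for Angpt1. The 10 lowest were Retnlg, Stfa2l1, Stfa1, Stfa2, S100a8, Stfa3, S100a9, Mmp8, Ifitm6 and Lcn2, from -8.07 for Retnlg to -6.47 for Lcn2. Early progenitor genes had 13 of 17 higher and 2 lower (median 2.12), the lower ones being Cebpa and Sfpi1 at -1.79 and -1.09, and S phase genes 13 of 18 higher (median 1.34), such as Pola1 at 1.58. Mitosis genes had a median of 0.67 with none at 2-fold, and cholesterol synthesis 0.63 with 2 of 15 higher. The other end held granulocyte genes with 10 of 14 lower and 3 higher (median -4.46), monocyte and macrophage genes with 14 of 15 lower (median -2.41), natural killer genes with 13 of 15 lower (median -1.53), dendritic cell genes with 9 of 15 lower (median -1.18) and B cell genes with 6 of 14 lower and 3 higher (median -0.68). Interferon response genes had 9 of 18 lower (median -1.01), inflammatory genes 8 of 13 (median -1.12), glucocorticoid response genes 9 of 12 (median -1.45), thymic stroma 8 of 13 (median -1.20) and lysosome genes 9 of 29 (median -0.62). Genes of p53 and cell death had 4 of 15 lower (median -0.77), and the autophagy and homing lists, with medians of -0.37 and -0.45, also lay below the random range. The autophagy list had 1 member higher and 3 lower, whereas the homing list had 3 higher and 2 lower. In this comparison 4 lists lay above and 13 below the random range. With a pseudocount of 5, 297 genes were higher and 633 lower. With a filter of 5 FPKM the autophagy (-0.35) and homing (-0.45) medians lay inside the random range.

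A further question was which differences of gl/gl were absent with the transgene. Of the 1048 genes higher in gl/gl than in wild type, 857 (81.8%) lay within 1.5-fold of wild type in CD2-Ostm1 gl/gl, and of the 790 lower genes 659 (83.4%) did. Cd34, Kit and Egfl7 were among the latter, while Mcpt1, Mcpt2 and Cma1 stayed lower, and Lars2 stayed higher at 237 FPKM against 46.1. Libraries differing by noise alone brought back 45.7% and 45.8%, but that simulation gave all 3 libraries equal noise. The observed fold changes against wild type had standard deviations across genes of 0.999 for gl/gl and 0.677 for CD2-Ostm1 gl/gl. The simulated shares are therefore no test of the observed shares. Of all measured genes, 90.5% lay within 1.5-fold between CD2-Ostm1 gl/gl and wild type, more than the observed shares of both directions. Those observed shares fell to 57.6% and 78.6% with a pseudocount of 0.1. Only the gl/gl library had Y-linked transcripts, and most granulocyte genes were far higher in it than in both others. Differences due to the sex or the cells of that pool would count as absent with the transgene too. They cannot be told apart here from an effect of the transgene.

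At least 2-fold in the same direction in both comparisons were 43 higher and 70 lower genes. Independent lists of these sizes would share 14.03 and 13.2, and the observed overlap was 4.10% of the 1048 higher and 8.86% of the 790 lower genes. In the opposite direction, 27 of the 1048 higher and 8 of the 790 lower genes differed by at least 2-fold between CD2-Ostm1 gl/gl and wild type. Noise alone with the shared wild type library gave lists of about 213 and 211 genes, of which 72.3 and 72.1 (33.9% and 34.1%) were shared. The lists of CD2-Ostm1 gl/gl against wild type held 172 and 215 genes. The observed shares of 1048 and 790 genes are therefore not like the simulated shares. Across genes the fold changes of both comparisons had a covariance of 0.222 and a correlation of 0.328. The values from noise alone, 0.229 and 0.5003, follow from giving all 3 libraries equal noise of this size. The observed fold changes had unequal standard deviations across genes, 0.999 for gl/gl and 0.677 for CD2-Ostm1 gl/gl against wild type. The simulated values are therefore no test of the shared library. With 1 wild type library the control cannot be split, so part or all of the excess over independent lists may come from that shared library.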

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

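Counts without predicted genes, clones and small RNAs and without X and Y genes were chosen after seeing the data, and the other settings were planned. No paired analysis was possible because the groups share only replicate number 1, with 1 library each. Removing the filter moved no count, since a 2-fold change on this scale needs 1 FPKM. Counts stayed within 1.5 times under the 5 FPKM filter, both rescalings and without X and Y genes. With a pseudocount of 0.1, CD2-Ostm1 gl/gl against wild type had 505 higher and 425 lower genes and CD2-Ostm1 gl/gl against gl/gl 1308 higher. With a pseudocount of 5 the counts (higher, then lower) were 520 and 347 for gl/gl against wild type, 49 and 91 for CD2-Ostm1 gl/gl against wild type, and 297 and 633 for CD2-Ostm1 gl/gl against gl/gl. In the same order, a threshold of 1.5-fold gave 2097 and 2073, 672 and 548, and 2160 and 2412, and one of 4-fold 304 and 145, 26 and 51, and 155 and 333, as a looser or stricter threshold must. Without predicted genes, clones and small RNAs 80 genes were higher in CD2-Ostm1 gl/gl than in wild type. The shares of higher and lower gl/gl genes back within 1.5-fold were 57.6% and 78.6% with a pseudocount of 0.1, and 77.6% and 68.3% for genes at least 4-fold different; the cause was not tested. A list median counted as kept if it stayed inside or stayed outside the random range, and direction was compared only for lists outside it. By this rule 96 of 99 were kept with a pseudocount of 0.1 and 95 of 99 after rescaling by the median of gene ratios. With the 5 FPKM filter, which left the platelet list too small, 88 of 96 were kept. Changes of sign among medians inside the random range were not counted. With a pseudocount of 0.1, gamma-delta T cell (-0.76, against gl/gl) and natural killer genes (-0.31, CD2-Ostm1 gl/gl against wild type) moved outside the random range and osteoclast genes (0.52, gl/gl against wild type) inside. With the 5 FPKM filter, the lists outside the random range in gl/gl against wild type gained dendritic cell (0.47) and immediate-early genes (0.33) and lost stroma (0.76), osteoclast (0.50) and autophagy (0.22). Those in CD2-Ostm1 gl/gl against gl/gl gained gamma-delta T cell (-0.72) and lost autophagy (-0.35) and homing (-0.45). After rescaling by the median of gene ratios, immediate-early genes lay outside in gl/gl against wild type (0.37) and, with T cell commitment (-0.32), in CD2-Ostm1 gl/gl against gl/gl (-0.39). The homing median of CD2-Ostm1 gl/gl against wild type turned to 0.0137. The causes of these shifts were not tested. Of 435 fold changes of named genes, 409 kept their side of 2-fold with a pseudocount of 0.1 and 428 after rescaling by the median of gene ratios, and none at 2-fold reversed direction. Depth limits low genes most, since 1 fragment on 1 kb is worth about 0.0372 FPKM in CD2-Ostm1 gl/gl and 0.0199 in wild type.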

Other observations

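The tests of scaling, of sex and of dilution below were chosen after the result they bear on was seen, whereas the shares of the second neutrophil list and of the second mast cell and basophil list were fixed before the values of their genes were looked up.

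Some further genes stood apart. A joint entry of Amd1 and Amd2, on the chromosome of Ostm1, had 10.6 FPKM in wild type, 0.0128 in gl/gl and 1.14 in CD2-Ostm1 gl/gl, while a separate entry of Amd2 at the same position had 58.1, 37.1 and 64.2. Within 20 Mb of Ostm1, 3 of 134 measured genes (2.24%) were at least 2-fold different in the same direction in both comparisons with wild type, namely Ostm1, the Amd1 and Amd2 entry and Snora33, against 110 of 12715 (0.865%) elsewhere. Ostm1 defines the window and is lost by genotype, and the separate Amd2 entry did not change alike. The shares are therefore not read as a local excess. Rn45s, the ribosomal RNA precursor, had 5593, 9820 and 9511 FPKM, and Lars2 had 46.1, 1018 and 237. Of the 14 measured members of the later alpha-beta T cell list, 2 were lower and 1 higher in gl/gl against wild type (median -0.19). The lower members were Cd8a and Cd8b1, with log2 fold changes of -1.93 and -1.79. The higher member was Klf2, a transcription factor of quiescent T cells, with 1.89. Genes measured on the X chromosome had a median of -0.20 in gl/gl against wild type, and those on autosomes -0.03.

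Of 14 granulocyte genes 10 were higher in the gl/gl library, with S100a8 at 14728 and S100a9 at 9344 FPKM, and 4 were lower (Mpo, Cpa3, Ctsg and Mcpt8). A single factor for that library would have raised all genes alike. The median of genes at 5 FPKM or more in all 3 libraries was -0.0619, so such a factor alone does not explain the granulocyte genes. How the deposited values were scaled is not stated, and scaling on typical genes would hold this median near 0 in any case. Of the 27 measured genes of a second neutrophil list, none of them in an earlier list and 18 of them at 1 FPKM or more in wild type, 96.3% were at least 2-fold higher in gl/gl, the exception being Clec4e. A candidate explanation is therefore granulocytes among the sorted cells, although a lineage-negative gate that includes granulocyte markers would remove them, and the antibodies of that gate are not given in the sources used here. The sex of the pooled mice cannot be told apart from the genotype, since 0 of the 3 genotypes had libraries of both sexes, and an effect of the gl/gl genotype on which cells enter the gate stays open, untested.

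Early progenitor genes were lower in the gl/gl library. Dilution of all other cells by added granulocytes would lower the T cell commitment genes alike if these came only from the diluted cells. Their median lay above that of the progenitor genes by 1.86 on the log2 scale, more than the larger of their interquartile ranges (1.55, against 0.834 for T cell commitment). In the same library 9 of 15 natural killer and innate lymphoid genes were higher (median 1.03). Whether such cells held up the T cell commitment genes was not tested, so this comparison does not decide about dilution. A single factor for the library would have lowered all genes alike, whereas the median of genes at 5 FPKM or more in all libraries was -0.0619. The limit given above, that the authors' scaling is not stated, holds for this value too. A lower share of early progenitors among the sorted cells may account for the pattern, as may lower transcription per cell or the sex of the pool, and none of these was tested.

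A set of 6 mast cell and basophil protease genes, chosen after their values were seen, was lower in both gl/gl libraries (Cma1 at 21.8 FPKM in wild type), with medians of -4.35 in gl/gl and -3.88 in CD2-Ostm1 gl/gl against wild type, but Cpa3, with 65.6 FPKM in wild type, had -3.81 and -0.68. Of other genes looked up for these cells, Gata2 had -2.51 and -1.47, Ms4a2 -0.83 and -0.63, and Hdc 3.96 and -0.28. Fcer1a was below 1 FPKM in all libraries. A single factor for the wild type library would have shifted all genes alike. The median over genes at 5 FPKM or more in all libraries was -0.0819, with the same limit that the authors' scaling is not stated. Mast cells or basophils in the wild type pool may be a source. Of a second mast cell and basophil list of 22 genes, 13 were measured, and the others were below 1 FPKM in every library, wild type included. But 5 of the 13 measured genes (38.5%) were at least 2-fold lower in CD2-Ostm1 gl/gl, between the bounds for and against that were set beforehand. In wild type, 12 of the 13 were at 1 FPKM or more. In gl/gl against wild type 4 of the 13 were higher and 3 lower (median 0.47), and of the 5 genes lower in CD2-Ostm1 gl/gl, Slc45a3 and Tph1 were lower in gl/gl too (0.346 and 0.127 FPKM against 4.66 and 2.62), Cd63 and Alox5 were higher (29.8 and 19.8 against 13.1 and 1.79), and Kcne3 had 3.04 against 4.10. Reads shared within the protease family make the single values uncertain, the lineage gate would remove such cells only if its antibodies cover them, and neither chance differences between pools of 2 and 3 mice nor an effect of the gl/gl genotype was tested.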
